A study of Mus musculus with 5 samples.

How the data were processed

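RNA was taken from 5000 purified Langerhans cells per library from the skin of mice aged 1 week, and libraries were made with an ultra-low-input protocol from polyadenylated RNA, per the labels' protocols. The 5 libraries were sequenced on a NextSeq 500 as paired-end reads of 75 bp, per the design text. The authors deposited raw counts per gene, as a table of the series and as a file per sample; reads were counted with featureCounts on mm10, per the submitters' processing notes. The aligner, the tool versions, the use of strand and the handling of reads that match several genes are not given in the sources used here, so values of overlapping genes, antisense genes and close paralogs are uncertain. The counts of the 5 files per sample were identical to those of the series table.

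The table holds 27179 NCBI gene identifiers. A symbol was found for 25293, of which 18 came from GENCODE vM21 and the rest from RefSeq on the assembly GRCm38.p6, whose coordinates are those of mm10. The 1886 identifiers without a symbol held 1.46% to 2.30% of the counts and stayed in the fit. One symbol of the gene lists was unmatched, an older name of a gene already listed.

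Libraries were assigned to wild type (2) or Suz12 cKO (3) by the genotype labels. The targeted gene and all named genes are given per library or as mean ± SD of TMM-normalised CPM, the count divided by the effective library size in units of 1e+06 counts. The main test was edgeR 4.0.16 (R 4.3.3), with filterByExpr at a minimum count of 10, TMM factors, and the robust quasi-likelihood F test on the group, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are cKO minus wild type. Where 1 group had no counts a lower bound was computed from 3 counts over the group, and with 1 to 3 counts a ratio with its 95% counting interval. The design, the gene lists, the rule for named genes and most of the alternatives were set before the data were examined.

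The rule named Suz12, Eed, Ezh2 and Ezh1; up to 10 genes per direction among those that passed with separate groups and a mean of at least 5 CPM in the higher group; in each list up to 4 members that passed, or 2 with the smallest p as values; and, with fewer than 10 passing in a direction, the 5 with the smallest p as values. One result under this rule is not reported here. Genes outside the rule were chosen after their values were seen: Cd207, Epcam, H2-Aa, Siglecf, Car4, Chil3, Marco, Ear2, Krt79, Krt14, Il1a, Il1b, Cxcl2, Cxcl1, Ccl3, Ccl4, Tnf, Il6, Xist, and those said to be so in the closing part.

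The 27 lists were tested with camera in limma 3.58.1 where at least 3 genes were tested, which left 23, with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, which tests whether the genes of a list move one way and does not compare them with other genes. They cover PRC2 and PRC1 subunits, Hox genes, developmental regulators, Cdk inhibitors, Langerhans cell identity, MHC class II, dendritic cell maturation, alveolar and dermal macrophages, monocytes, neutrophils, keratinocytes, melanocytes, fibroblasts and endothelium, T cells, mast cells, S phase, G2 and M phase, p53 targets, interferon response, inflammatory mediators, TGF-beta signalling, lipid metabolism, lysosome, dissociation response and sex-linked genes. With fry, inflammatory mediators and developmental regulators had adjusted p-values of 0.0214 each for change one way. For change in either direction they had 0.0511 and 0.231. Cdk inhibitors had 0.184 one way and 0.0405 in either direction with fry.

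Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, a minimum count of 50, limma-voom with quality weights, a fit that is not robust, a replicate block, the style of the sample titles as a term, each library left out, the files per sample, and glmTreat at a log2 fold change of 1. A further 2 were added after seeing the data, edgeR without its legacy setting and a minimum mean of 50 CPM. To look for duplicate deposits of a library, same-group libraries were compared by chi-square, and no pair agreed within counting noise (182 to 410 per degree of freedom), as separate samples are expected not to. The fits were tested on simulated counts, as were the list tests. There a 20-gene list moved 2-fold had a camera p of 2.7e-05 and 0 of 20 unmoved lists had a p under 0.05. The simulated genes were drawn independently, so this does not test camera on lists whose genes vary together. The estimated correlation was 0.166 for the keratinocyte list, 0.181 for G2 and M phase and -0.0447 for inflammatory mediators. With these libraries the other 9 splits into 2 and 3 gave 1 to 4 lists past the threshold of camera, against 3 with the real groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.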

Results

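Messenger RNA was profiled in Langerhans cells, the resident phagocytes of the epidermis, purified from the skin of C57BL/6 mice aged 1 week. The mice were wild type (2 biological replicates) or carried a conditional knockout of Suz12, written Suz12 cKO (3 biological replicates). Suz12 is a core subunit of Polycomb repressive complex 2 (PRC2), which methylates histone H3 at lysine 27. Each library was made from 5000 cells. The counts assigned to genes came to 18656968 and 17041996 in the wild type libraries, and to 17384033, 25725900 and 12090062 in the cKO libraries. Between 9103 and 10220 genes had at least 1 count in a library. A gene with no count could lie at up to 0.106 to 0.258 CPM (counts scaled to a common library size), the value of 3 counts in the deepest and the shallowest library. Such floors, and the intervals given for counts, cover counting error only, because amplified reads without molecular identifiers are not independent molecules.

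The libraries carried the transcripts of Langerhans cells. Cd207, which encodes langerin, lay at 7584 and 7417 CPM in the wild type libraries and at 14597, 6639 and 8393 CPM in the cKO libraries. Epcam, an adhesion molecule of Langerhans cells, lay between 1042 and 1634 CPM, and the MHC class II gene H2-Aa between 18154 and 25104 CPM. The source label names alveolar macrophages as the source of all 5 libraries, while the titles, the tissue and the protocol name Langerhans cells of skin. The alveolar macrophage genes Siglecf, Car4 and Chil3 had no count in any library, and Marco was above 1 CPM in wild type replicate 1 alone, at 45.7 CPM. Of the 22 genes fixed as alveolar macrophage markers, 9 had enough counts to test, among them Ear2 and Krt79. Across the Langerhans cell identity list, all 28 genes were tested, 16 lay higher and 12 lower in the cKO libraries, and the median log2 fold change was 0.12 (camera adjusted p = 0.758). In that list, the lectin gene Cd209a lay at 545 ± 176 CPM in wild type (SD, n = 2) and 103 ± 55.5 CPM in cKO (SD, n = 3). It did not pass the test over all genes (edgeR adjusted p = 0.968).

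Suz12 itself was scarce in every library. The gene (chromosome 11, 79993106 to 80034123, mm10) had 88 and 39 counts in the wild type libraries and 0, 0 and 7 counts in the cKO libraries. These counts correspond to 4.66 CPM (95% exact Poisson interval 3.74 to 5.74) and 2.30 CPM (1.63 to 3.14) in wild type, and to 0.601 CPM (0.242 to 1.24) in cKO replicate 3. All 3 cKO libraries lay below both wild type libraries, in the direction of the genotype labels. The fitted log2 fold change was -4.11 with a standard error of 2.87, which did not pass the test (edgeR adjusted p = 0.999). A conditional allele can leave exons outside the deleted part transcribed, and the counts are per gene, so they do not show which exons the 7 counts came from. The other core PRC2 genes did not pass either. Eed lay at 50.1 ± 22.0 CPM in wild type and 80.4 ± 67.6 CPM in cKO (SD, n = 2 and n = 3), and its log2 fold change of 0.68 turned to -0.26 without cKO replicate 1. Ezh2, the catalytic subunit, had a log2 fold change of 0.44 with a standard error of 0.94, and its paralog Ezh1 one of 1.06 with a standard error of 1.37. Over the 11 tested PRC2 subunits, 6 lay higher and 5 lower, with a median of 0.16 and a mean of -0.12 (camera direction down, adjusted p = 0.802). Among 13 tested PRC1 subunits 11 lay higher and 2 lower, with a median of 1.14 (camera adjusted p = 0.868). In that list Cbx6 had 78 counts over both wild type libraries and none in cKO, at least 40.5-fold lower with the floor set over the group, and Ring1 had none in wild type and 4.60 and 3.61 CPM in cKO replicates 2 and 3.

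The comparison of genotypes asks which transcripts of Langerhans cells depend on Suz12. Among the genes with the smallest p-values on the higher side in cKO, Cxcl3, a chemokine that attracts neutrophils, lay at 20.2 ± 1.06 CPM in wild type and 207 ± 54.9 CPM in cKO (SD, n = 2 and n = 3), a log2 fold change of 3.36 with a standard error of 0.45. Il10, an anti-inflammatory cytokine, had 1 count over both wild type libraries and lay at 404, 32.3 and 159 CPM in the cKO libraries. The ratio was 5914, with a counting interval from 1061 to 233624. Gem, a small GTP-binding protein, lay at 51.6 ± 30.9 and 397 ± 125 CPM, Arhgef3 at 2.13 ± 2.01 and 87.6 ± 11.1 CPM, and the co-chaperone gene Dnajb2 at 0.112 ± 0.00853 and 46.3 ± 44.9 CPM. On the lower side, Lyz2, the lysozyme of myeloid cells, lay at 1591 ± 721 CPM in wild type and 556 ± 74.2 CPM in cKO, a log2 fold change of -1.52 with a standard error of 0.35. Reads of Lyz2 can be shared with its close paralog Lyz1. Cd209a had a log2 fold change of -2.40 with a standard error of 0.57. Capsl lay at 123 ± 15.7 and 24.3 ± 10.6 CPM, and Cnih1 at 173 ± 5.62 and 62.0 ± 9.35 CPM. Sertad3 lay at 32.4 and 44.9 CPM in wild type and had no count in cKO, at least 713-fold lower with the floor set over the group.

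None of these genes passed the main test. edgeR called 0 of 9988 tested genes at an adjusted p of 0.05, with 0 higher and 0 lower, and the smallest adjusted p was 0.968. At an unadjusted p of 0.05, 210 genes lay higher and 205 lower, 415 in all, where chance alone would give 499.4. DESeq2 called 191 genes, 137 higher and 54 lower, and 149 of them had fewer than 10 counts in every library of 1 of the groups. In a set limited to the 2675 genes with a mean of at least 50 CPM, which was chosen after seeing the data, edgeR called Il10, Cxcl3 and Gem, with adjusted p-values of 0.0243, 0.0243 and 0.0473. The adjusted p of Cxcl3 over all settings was lowest with DESeq2, at 3.18e-08. The libraries differed from one another about as much within a genotype as between genotypes: Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.631 between the wild type libraries, 0.574 to 0.594 among the cKO libraries and 0.581 to 0.610 between groups. The p-values measure the spread between these libraries. Of the tested genes 3682, or 36.9%, lay at 10 CPM or more in one library and under 1 CPM in another. In simulated counts with the dispersions of these libraries and 9043 genes tested, edgeR recovered 0% of genes changed 2-fold, 2.22% of those changed 4-fold and 28.3% of those changed 16-fold. A call of 0 genes therefore does not exclude changes of these sizes.

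As a group, genes for inflammatory mediators rose in cKO relative to other genes. Of 20 tested genes of this list, 12 lay higher and 8 lower, with a median log2 fold change of 0.46, and camera with a preset inter-gene correlation of 0.01 gave an adjusted p of 0.000585. With an estimated correlation the list did not pass camera (unadjusted p = 0.0194, adjusted p = 0.446). The estimate was -0.0447, below the preset value, so the larger p does not come from genes of this list varying together. All 3 cKO libraries lay above both wild type libraries for 6 of the 20 genes and below both for 1. Over all tested genes the groups did not overlap, in either direction, for 1901 (19.0%). Chance would give up to 20%, and less where libraries without a count tie, since ties were counted as overlap. With fry, which does not compare a list with other genes, the adjusted p was 0.0214. Over all genes none of the members was called, and 3 passed when adjusted over the list alone: Cxcl3, Il10 and Il1a. Il1a, the cytokine interleukin 1 alpha, lay at 105 ± 31.9 CPM in wild type and 452 ± 173 CPM in cKO (SD, n = 2 and n = 3). The neutrophil chemokine Cxcl2 lay at 2196 ± 526 and 4240 ± 350 CPM, and Ccl3 at 38.0 ± 26.1 and 183 ± 93.7 CPM. Ccl3 and Ccl4 overlap in the annotation and Cxcl1, Cxcl2 and Cxcl3 are related in sequence, so reads may not be assigned to one of them alone. Other members of the list went the opposite way or showed no difference: Il1b lay at 5689 ± 1247 and 4935 ± 1521 CPM, Tnf at 210 ± 28.5 and 155 ± 52.8 CPM, and Il6 had a log2 fold change of -1.81 with a standard error of 2.09. The adjusted p of the list was 0.173 without wild type replicate 1 and 0.0982 without wild type replicate 2, and it ranged from 1.68e-08 to 0.446 over 17 alternatives. Keratinocyte transcripts also lay higher in cKO as a list, and sex-linked transcripts differed between libraries, as given below.

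**Figure D1:**
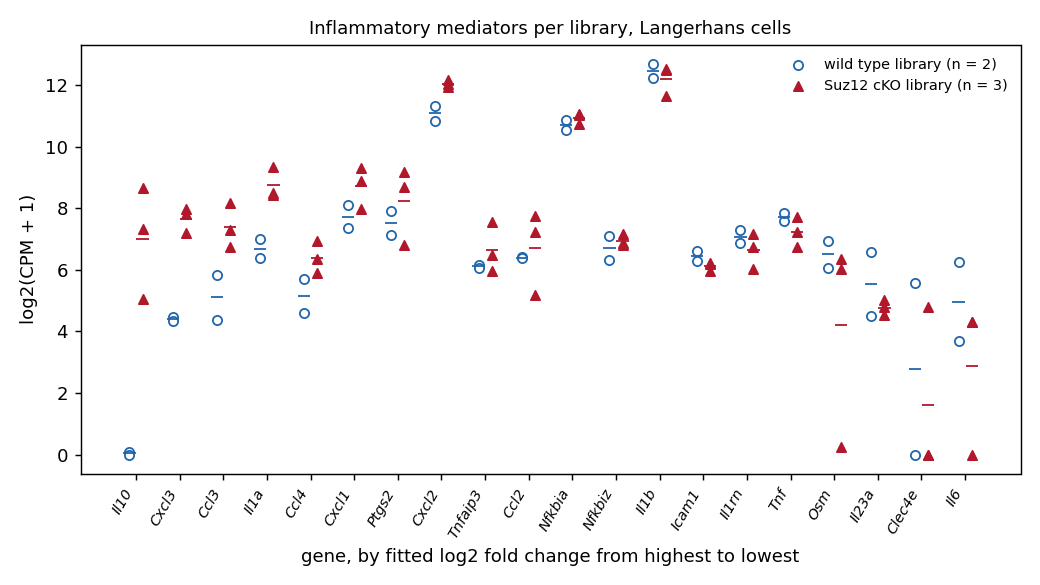
Expression of the 20 tested inflammatory mediator genes as log2(CPM + 1) on the vertical axis, with genes on the horizontal axis in order of fitted log2 fold change; open circles are the 2 wild type libraries, triangles the 3 Suz12 cKO libraries and short lines the group means. Il10, Cxcl3, Ccl3, Il1a, Ccl4 and Cxcl2 have every cKO library above both wild type libraries, and Il1b, Tnf and Il6 do not.

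Transcripts of keratinocytes, the epithelial cells that surround Langerhans cells, were more abundant in cKO as a list. Of 21 tested genes 17 lay higher and 4 lower, with a median log2 fold change of 0.88 (camera adjusted p = 0.00692, and adjusted p = 0.636 with an estimated correlation). Krtdap, a gene of differentiating keratinocytes, lay at 61.1 ± 22.2 CPM in wild type and 202 ± 117 CPM in cKO (SD, n = 2 and n = 3), and Krt10 at 17.2 ± 11.6 and 72.1 ± 40.4 CPM. The basal keratin Krt14 had a log2 fold change of 0.02 with a standard error of 0.50. Over 4 basal keratins, Krt14 among them, the mean change on the log2(CPM + 1) scale was 0.705 (95% interval between libraries -2.23 to 3.64). The summed level of the list was 461 CPM in wild type replicate 1, 1225 CPM in wild type replicate 2 and 1313 to 1579 CPM in cKO, and without wild type replicate 1 the adjusted p was 0.421, within a range of 0.00017 to 0.636 over the alternatives. Markers of other skin and blood cells did not pass with all 5 libraries, but the melanocyte list passed without wild type replicate 1 (adjusted p = 0.00316, range up to 0.921) and the T cell list without cKO replicate 1 (0.0143, range up to 0.991). All 5 tested melanocyte genes lay lower, with a median of -1.85 (camera adjusted p = 0.421). Most of the difference came from wild type replicate 2, where the list summed to 437 CPM against 39.6 CPM in wild type replicate 1. In cKO replicates 1 to 3 it summed to 49.9, 33.1 and 146 CPM. Dct and Mlana, both of the melanocyte list, had log2 fold changes of -1.85 each, with standard errors of 1.44 and 2.15. Without wild type replicate 2 these became 0.15 and 10.78. The value for Mlana is fitted and not a measured fold, since wild type replicate 1 had no count of it. Of 13 tested T cell genes 4 lay higher and 9 lower (median -0.16, mean 0.29, camera direction down, adjusted p = 0.257). Cd3d lay at 86.7 ± 27.0 and 32.9 ± 10.2 CPM, while Cd96 had 2 counts over both wild type libraries, 286 and 384 counts in cKO replicates 1 and 2 and none in cKO replicate 3. The 6 tested genes of fibroblasts and endothelium had a median of 0.05 (adjusted p = 0.802); Egfl7 had no count in wild type and in cKO replicate 2 and had 95 and 128 counts in cKO replicates 1 and 3, and Dcn ranged from 0 to 136 CPM across the libraries. In the neutrophil list 2 of 12 genes could be tested, Mmp9 at 178 ± 10.3 and 334 ± 164 CPM and Csf3r with 1 count over both wild type libraries, 151 and 368 counts in cKO replicates 1 and 2 and none in cKO replicate 3. The mast cell list had 1 tested gene, Gata2, which had no count in wild type and in cKO replicate 1, and 164 and 26 counts in cKO replicates 2 and 3.

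The macrophage, monocyte and lysosome lists did not pass. In the dermal macrophage list 5 of 13 genes lay higher and 8 lower (median -0.30, mean 0.43, camera direction down, adjusted p = 0.567, and direction up without wild type replicate 1, 0.726). C1qb, a complement gene, lay at 151 ± 47.8 CPM in wild type and 74.2 ± 28.2 CPM in cKO (SD, n = 2 and n = 3), and the phagocytic receptor gene Timd4 at 4.76 ± 3.98 and 43.2 ± 38.5 CPM. The monocyte list had 3 genes higher and 4 lower (median -1.31, mean 0.49, camera direction down, adjusted p = 0.718, and direction up without wild type replicate 1, 0.925). Lyz2 passed when adjusted over the list alone and not over all genes, and Vcan had no count in wild type and in cKO replicate 3, and lay at 9.45 and 15.2 CPM in cKO replicates 1 and 2. Among the alveolar macrophage genes 3 lay higher and 6 lower, with a median of -0.54 (adjusted p = 0.171). Il18, which encodes interleukin 18, lay at 130 ± 7.61 and 69.5 ± 19.1 CPM, and the zinc transporter gene Slc39a2 had 114 and 224 counts in wild type replicates 1 and 2 and no count in cKO. For lysosomal genes, 10 lay higher and 10 lower (median 0.06, mean 0.03, camera direction down, adjusted p = 0.868). Cd68, a lysosomal glycoprotein of phagocytes, lay at 635 ± 72.2 and 295 ± 77.4 CPM, and Npc2 at 463 ± 76.8 and 335 ± 19.5 CPM.

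Genes of the G2 and M phases of the cell cycle lay lower in cKO as a list, but not to the same degree in the 3 cKO libraries. The list summed to 2009.5 and 1897.3 CPM in wild type and to 1079.7, 1374.7 and 1722.1 CPM in cKO replicates 1 to 3. The median over its genes was 21.5 and 24.9 CPM in wild type and 1.69, 20.04 and 29.2 CPM in cKO replicates 1 to 3. By that median cKO replicate 1 lay far below the other libraries, and cKO replicate 3 lay above both wild type libraries. Of 33 tested genes 10 lay higher and 23 lower, with a median log2 fold change of -0.59 and all cKO libraries below both wild type libraries for 7 and above both for 1 (camera adjusted p = 0.0214, and adjusted p = 0.801 with an estimated correlation). An unadjusted camera p as small as that of the real groups came from 4 of the 10 splits of the libraries, the real one included. The mean over the list was 0.05, or -0.07 with the genes that were at 0 in 1 group set to their bound, so the median and the fitted mean differed in sign. Smc4, a condensin subunit, lay at 168 ± 44.6 CPM in wild type and 34.0 ± 27.9 CPM in cKO (SD, n = 2 and n = 3), whereas the mitotic kinesin gene Kif20b had no count in wild type, 2 counts in cKO replicate 1, which is under the floor of 3, and 17.1 and 44.0 CPM in cKO replicates 2 and 3. The adjusted p of the list was 0.184 without wild type replicate 1, 0.197 without wild type replicate 2, 0.542 without cKO replicate 1, 0.179 with DESeq2 and 0.0613 with the style of the sample titles as a term, within a range of 9.08e-05 to 0.801 over the alternatives. S phase genes were divided, with 12 higher and 13 lower (median -0.01, mean 0.05, camera direction down, adjusted p = 0.802). Tipin lay at 45.3 ± 3.22 and 94.0 ± 17.1 CPM, and the ribonucleotide reductase gene Rrm1 at 50.7 ± 14.7 and 109 ± 30.6 CPM. Of 7 genes for inhibitors of cyclin-dependent kinases 5 lay higher and 2 lower, with a median of 1.09 (camera adjusted p = 0.0961). With fry the adjusted p was 0.184 for change one way and 0.0405 for change in either direction. This list passed with the stricter filter (adjusted p = 0.0185) and without cKO replicate 1 (0.0414), within a range of 0.0185 to 0.636 over the alternatives. Cdkn1a, the p21 inhibitor, lay at 1095 ± 90.9 CPM in wild type and 1975 ± 570 CPM in cKO, a log2 fold change of 0.85 with a standard error of 0.33. Cdkn2b had no count in wild type and lay at 0.25, 18.4 and 10.6 CPM in the cKO libraries. In the list of p53 targets and apoptosis genes 15 lay higher and 4 lower, with a median of 0.42 (adjusted p = 0.171, and 0.00431 with a minimum mean of 50 CPM, within a range up to 0.636), and Ccng1, which encodes cyclin G1, lay at 24.9 ± 30.4 and 138 ± 55.6 CPM.

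Developmental genes that PRC2 silences in many tissues were mostly undetected in both genotypes. Of 136 Hox and developmental regulator genes, 8 and 8 reached 10 counts in the wild type libraries and 11, 11 and 14 in the cKO libraries. The difference of 4 genes had a p of 0.1 by a two-sided exact permutation test, which is the smallest p that the 10 splits of 2 against 3 libraries can give. Sox9, a transcription factor of epithelial and cartilage development, had no count in wild type and lay at 13.6, 14.3 and 20.8 CPM in cKO. That is at least 185-fold higher by counting error alone, and Sox9 did not pass the test over all genes (edgeR adjusted p = 0.968). Bmp7 went the other way, with 1.32 and 7.72 CPM in wild type and no count in cKO. Over the 11 developmental regulators that could be tested 6 lay higher and 5 lower, with a median of 0.15 and a mean of 1.41 (1.05 with the genes that were at 0 in 1 group set to their bound). Camera, which compares the list with other genes, gave an adjusted p of 0.257, and fry, which does not, gave 0.0214. Of the Hox genes 1 of 39 could be tested, Hoxc8, with 26 counts in wild type and 148 in cKO, all of the latter in cKO replicate 3. The libraries also held transcripts of other skin cells, so these values do not show which cells the developmental transcripts came from. The fibroblast and endothelium list summed to 357 CPM in cKO replicate 3 and 224 CPM in wild type replicate 2, against 19.1 to 87.9 CPM elsewhere. The titles of cKO replicate 3 and wild type replicate 2 spell out the cell type, and the other titles abbreviate it. Whether the title style marks a preparation batch is not given.

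Antigen presentation and other functions of Langerhans cells showed no list past the threshold with all 5 libraries. In the MHC class II list 7 lay higher and 6 lower (median 0.04, mean -0.15, camera direction down, adjusted p = 0.802), and H2-Aa had a log2 fold change of -0.02 with a standard error of 0.26. Ifi30, a lysosomal thiol reductase, lay at 527 ± 186 CPM in wild type and 320 ± 98.0 CPM in cKO (SD, n = 2 and n = 3), and H2-Oa at 33.1 ± 18.6 and 78.1 ± 40.9 CPM. Dendritic cell maturation and migration genes had 13 higher and 5 lower, with a median of 0.54 (camera adjusted p = 0.257, and 0.0155 without cKO replicate 2, within a range up to 0.975). Tnfrsf9, a costimulatory receptor, had no count in wild type and lay at 39.2, 11.1 and 15.4 CPM in cKO, and Cd200 had no count in wild type and 33, 123 and 16 counts in the cKO libraries. For TGF-beta signalling, which Langerhans cells require, 15 lay higher and 4 lower, with a median of 0.61 (adjusted p = 0.143); the receptor gene Bmpr1a had no count in wild type and 356, 3 and 114 counts in the cKO libraries, and Ltbp1 had no count in wild type and in cKO replicate 1, and 83 and 30 counts in cKO replicates 2 and 3. Cholesterol and fatty acid genes had 17 higher and 10 lower (median 0.16, adjusted p = 0.802), among them the fatty acid receptor gene Cd36, at 2.20 ± 1.47 and 45.8 ± 14.4 CPM, and Lss, with 28 and 152 counts in wild type replicates 1 and 2 and no count in cKO. Interferon response genes were split 11 to 11 (median 0.00, mean -0.36, adjusted p = 0.802), and Ifit3 and Ifit3b, near-identical neighbours that can share reads, had no count in cKO, and 296 and 30 counts (Ifit3) and 106 and 254 counts (Ifit3b) in wild type replicates 1 and 2. Of 29 dissociation and heat shock genes 19 lay higher and 10 lower (median 0.21, adjusted p = 0.802), with Nr4a2 at 168 ± 98.5 and 350 ± 110 CPM and Dnaja1 at 155 ± 10.6 and 231 ± 77.4 CPM.

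**Figure D2:**
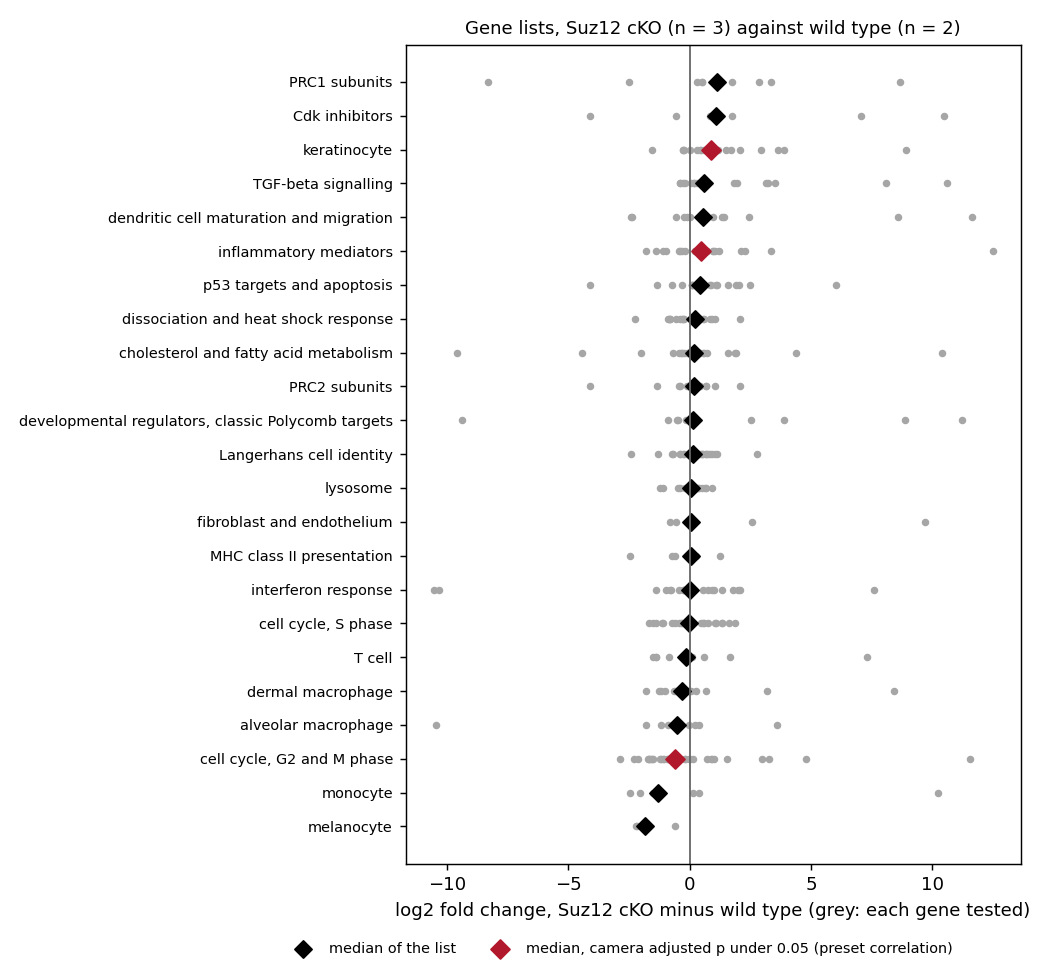
Log2 fold change of Suz12 cKO minus wild type on the horizontal axis for the 23 tested gene lists on the vertical axis; grey points are single genes and diamonds are list medians, red where camera with the preset correlation gave an adjusted p under 0.05. The 3 red lists are inflammatory mediators (median 0.46), keratinocyte (0.88) and G2 and M phase (-0.59), and none of them passed with an estimated correlation.

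Sex-linked transcripts differed between libraries. Xist, which is transcribed from the inactive X chromosome of females, lay at 69.1 CPM in wild type replicate 2 and had no count in the other libraries. The Y-linked gene Ddx3y lay at 78.4 CPM in wild type replicate 1, 0.059 CPM in wild type replicate 2 and 53.9 to 86.8 CPM in cKO. Eif2s3y, also Y-linked, lay at 1.38 CPM in wild type replicate 1, had no count in wild type replicate 2 and lay at 61.0 to 105 CPM in cKO. Eif2s3y passed when adjusted over the list alone and not over all genes (edgeR adjusted p = 0.968).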

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

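Of the alternatives below, 2 were chosen after seeing the data: the minimum mean of 50 CPM and edgeR without its legacy setting. edgeR called 0 genes with the settings of the report and in 14 of 16 other settings, and limma-voom called 0. DESeq2 called 191 genes (137 higher, 54 lower), the replicate block called 1 (higher, Il10) and the minimum mean of 50 CPM called 3 (all higher). No pairing of the libraries by replicate number is given, and only 2 numbers are shared, so the block has no basis beyond the number. The deviations of same-numbered libraries correlated at -0.023 and -0.0052. The 2 wild type libraries deviate from their mean by equal and opposite amounts, so these values cannot exclude a pairing. With the block the inflammatory mediator list had an adjusted p of 0.0551. The unadjusted p fell under 0.05 for 163 to 857 genes over the settings. Suz12 was lower in cKO under all 16 alternatives that tested it, with log2 fold changes from -9.12 to -3.50; the stricter filter and the minimum mean of 50 CPM left it out. Of 59 genes under the naming rule 52 kept their direction under each alternative that gave them a value (14 to 18 per gene), and of 23 lists 9 did (16 to 17 per list). DESeq2 moved 17 of these genes past the threshold, and other edgeR settings moved 3. With each library left out in turn the count stayed at 0.

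The direction of single genes turned as follows, and none of these was past the threshold. Without one library, the range of log2 fold change was -0.26 to 1.20 for Eed, -4.60 to 0.15 for Dct, -2.84 to 10.78 for Mlana, -0.16 to 12.87 for Dcn and -0.19 to 10.04 for Ddx3y. The upper values of Mlana and Dcn were fitted with a remaining wild type library that had no count of them, so they are not measured folds. The upper value of Ddx3y rests on 1 count in wild type replicate 2, the only library with counts of Xist. With the replicate block Ezh2 was at -0.0106, Hoxc8 at -4.79 and Mlana at 2.52; with the title style as a term Hoxc8 was at -4.94 and Mlana at 2.75; with limma-voom Mlana was at 2.84. The cause was not tested.

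The number of lists past the threshold was 3 with the settings of the report, 1 to 4 with a library left out and 0 with an estimated correlation. Adjusted p-values with an estimated correlation were 0.446 for inflammatory mediators, 0.636 for keratinocyte and 0.801 for G2 and M phase. The G2 and M list was also at 0.179 with DESeq2 and 0.0613 with the title style as a term. With a library left out the adjusted p ranged from 0.00166 to 0.173 for inflammatory mediators, 0.00017 to 0.421 for keratinocyte and 9.08e-05 to 0.542 for G2 and M phase. In lists whose direction turned, adjusted p-values were, with a library left out, 0.618 to 0.991 for PRC2, 0.564 to 0.988 for PRC1, 0.707 to 0.991 for MHC class II, 0.0155 to 0.799 for dendritic cell maturation, 0.206 to 0.726 for dermal macrophage, 0.376 to 0.925 for monocyte, 0.00316 to 0.674 for melanocyte, 0.197 to 0.678 for fibroblast and endothelium, 0.0143 to 0.991 for T cell, 0.449 to 0.988 for S phase, 0.197 to 0.800 for interferon response, 0.542 to 0.834 for lipid metabolism, 0.376 to 0.991 for lysosome and 0.191 to 0.888 for dissociation. PRC2 also turned with the stricter filter (0.860) and the minimum mean of 50 CPM (0.792), MHC class II with limma-voom (0.967) and the minimum mean (0.823), S phase with DESeq2 (0.847) and the minimum mean (0.7945), lysosome with the block (0.975) and the minimum mean (0.823), and fibroblast and endothelium with the block (0.975). The cause was not tested. Lists that passed camera only under an alternative were Cdk inhibitors with the stricter filter (0.0185) and without cKO replicate 1 (0.0414), p53 targets at the minimum mean of 50 CPM (0.00431), dendritic cell maturation without cKO replicate 2 (0.0155), melanocyte without wild type replicate 1 (0.00316) and T cell without cKO replicate 1 (0.0143). With 1 wild type library left, that library is assumed to vary like the cKO libraries.

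The spread between libraries limits the comparison. In simulated counts for this design edgeR recovered 58% of 2-fold and 98% of 4-fold changes at a dispersion of 0.05, against 0% and 2.22% at the dispersions of these libraries. The median standard error of a log2 fold change was 2.97 for genes under a mean log2 CPM of 4 and 0.356 for those over 8, and the common dispersion was 1.93. In the simulation DESeq2 recovered 56.5% of genes changed 16-fold, against 28.3% with edgeR, but also called 181 of 8863 unchanged genes, where edgeR called 2.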

Other observations

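The genes in this paragraph were chosen after their values were seen, and none passed the test over all genes (edgeR adjusted p = 0.968 for each). Several genes of macrophages lay lower in all cKO libraries than in both wild type libraries. Ms4a7 lay at 128 and 102 CPM in wild type and at 0.375, 9.59 and 0.258 CPM in cKO, Mpeg1 at 107 and 76.1 against 22.0, 8.50 and 24.4 CPM, and Cd209e at 486 and 226 against 54.4, 89.1 and 149 CPM. Mmp12, at 557 and 96.1 against 59.6, 74.6 and 84.7 CPM, rested mostly on wild type replicate 1. In the other direction Rel, an NF-kappa-B subunit, lay at 26.7 and 18.9 CPM in wild type and 106, 117 and 143 CPM in cKO, Ctnnb1 at 7.25 and 6.54 against 46.0, 133 and 86.7 CPM, Serpinb9 at 34.2 and 38.4 against 126, 148 and 152 CPM, and Gpr171 at 188 and 122 against 812, 365 and 624 CPM. Cdkn2a, a locus that PRC2 silences in many cells, had 1 count over both wild type libraries and lay at 7.95, 1.73 and 4.81 CPM in cKO.

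All tests of explanations in the following paragraphs were chosen after the results were seen. DESeq2 called 191 genes where edgeR called 0. The other splits of the 5 libraries into 2 and 3 gave 122 to 297 DESeq2 calls, with a median of 166. DESeq2 thus called many genes whichever libraries were grouped. All-or-none detection in single libraries may contribute, but the splits do not separate it from other spread between libraries. As many calls as in the real split came from 2 of the 10 splits, the real one included, and the highest of the others was 297; 10 splits are too few for a share under 0.05. An effect of the genotype on part of the 191 genes stays open.

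The inflammatory mediator list lay higher in cKO. Neutrophils in the cKO libraries are argued against as the source of the rise of Cxcl2. S100a8 and S100a9, among the most abundant neutrophil transcripts, together rose by at most 0.00366 of that rise in CPM. They reached at most 6.27 CPM in a cKO library. The 2 tested genes of the neutrophil list went the other way, with Mmp9 higher in every cKO library and Csf3r in cKO replicates 1 and 2. The ratio was not computed for other members of the inflammatory list. A response to tissue dissociation stays open, since the inflammatory list's median minus the dissociation list's had a bootstrap 95% interval over genes from -0.596 to 0.923. The sex of the animals stays open too. Without the wild type library that carries Xist the adjusted p was 0.0982 and the list rested on 1 wild type library. The list's median log2 fold change went from 0.457 (bootstrap 95% interval -0.358 to 1.004, 20 genes) to 0.673 (0.300 to 1.62, 22 genes). The bootstrap intervals of this paragraph come from redrawing genes within a fit, so they do not measure the spread between libraries. The median of all tested genes rose as well, from 0.058 to 0.372, so the rise of the list's median does not argue against sex. Without the other wild type library the medians were 0.731 (-0.0635 to 1.66) for the list and 0.285 for all tested genes. The list did not pass there either, so the lost call is not particular to sex. The real split had a camera p of 2.54e-05, as small in 1 of the 10 splits, and the smallest among the others was 0.0157; 10 splits are too few for a share under 0.05. An effect of losing Suz12 is a hypothesis that these libraries leave open.

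Keratinocyte transcripts lay higher in cKO. A lower share of Langerhans cells in the cKO libraries would raise the markers of every other cell type, and stays open: on the log2(CPM + 1) scale the keratinocyte genes moved by 0.987 more than the 27 genes of T cells, melanocytes, fibroblasts and endothelium, neutrophils and mast cells, with a 95% interval between libraries from -0.152 to 2.12 (0.0572 to 2.37 without cKO replicate 3, and including 0 without each of the other 4). Against the T cell and melanocyte genes alone, 1 of 7 comparisons run, it was 1.47 (0.208 to 2.72), and the interval included 0 without any 1 library other than wild type replicate 2 (-0.356 to 2.38 without wild type replicate 1). More keratinocyte RNA of every layer could not be excluded, because the mean change of 4 basal keratins had an upper 95% limit of 3.64, and how the skin was processed was not tested. A camera p as small as the real one, 0.000602, came from 2 of the 10 splits, the real one included, and the smallest among the others was 8.9e-06; 10 splits are too few for a share under 0.05. For the G2 and M phase list it was 4 of 10 splits. The real split gave 3 lists past the threshold of camera and the other 9 splits gave 1 to 4.

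Eif2s3y and Ddx3y, which are both Y-linked, did not go together in wild type replicate 1, at 1.38 and 78.4 CPM.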
